A study of Mus musculus with 13 samples.

How the data were processed

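The series holds 13 libraries of live sorted single cells from mammary tumours of FVB/NJ mice in which HER2 was induced in mammary tissue at 1 month of age. Antibody was given weekly once tumours could be felt (200 mm^3). Per the labels, 4000 to 6000 sorted cells went into each Chromium 5' reaction with 4000 as the target. Samples 1 to 10 were sequenced on a NovaSeq and 11 to 13 on a HiSeq X. If samples were counted in deposition order, the last 3 are combination replicates 2 to 4. The authors used Cell Ranger 2.2.0 and Seurat 2.3.4 with the mouse genome, a human genome and an added human ERBB2 transcript.

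Each library came as a table of 31054 genes by cells. The deposited values are the natural log of 1 + UMI count x 10000 / total UMI count of the cell. Tested on each file, every cell's back-transformed values summed to 10000 and were whole multiples of the cell's smallest value, so UMI counts per cell could be recovered exactly. The authors had already filtered the cells. The highest UMI total of a cell was 29827 in control, 39973 in anti-CD47, 44988 in anti-HER2 and 34968 in combination libraries, and the highest gene count 4999, 5998, 6824 and 5990. No cell had over 10% mitochondrial UMIs.

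Recovered depth per library was 22880578, 17691790 and 25364159 UMIs in control replicates 1 to 3. It was 29296245 and 37665255 in anti-CD47 replicates 1 and 2, and 43929148, 43125134, 61914595 and 41319238 in anti-HER2 replicates 1 to 4. Combination replicates 1 to 4 held 37069695, 30599245, 82301317 and 55347905 UMIs. Macrophage-like cells alone held from 2188287 UMIs (combination replicate 4) to 12507278 UMIs (anti-HER2 replicate 3).

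Groups follow the labels: control (1 isotype and 2 untreated libraries, pooled because both carry the untreated tag), anti-CD47 (clone MIAP410), anti-HER2 (4D5-IgG2A) and the combination of both. Library tags share a number between an A and a B library. The labels do not say whether such a pair comes from 1 animal, so p-values measure the spread between libraries and are too small if it does. Deviations from the group mean in macrophage-like cells correlated at 0.512 and 0.330 for the pairs of anti-HER2 libraries that share a number and at -0.0173 and -0.150 for those of the combination. Pairs without a shared number lay lower, at -0.581 to -0.794 for anti-HER2 and -0.421 to -0.510 for the combination. A fit with 1 value per tag number and a fit with the number as a random effect (correlation 0.242) were run as alternatives. Both anti-CD47 libraries carry the same number, so the first of these fits held 1 anti-CD47 value. Its spread was taken from the other groups. No pair of libraries was as alike as a duplicated library would be.

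Cells with at least 500 UMIs, 300 genes and at most 15% mitochondrial UMIs were kept, which removed 0. Doublets were scored in each library against simulated pairs, and the top 0.8% per 1000 cells (1219 cells, 3.25%) were marked. They stayed in the clustering and were left out of sums and shares. Clustering used 2000 variable genes, 30 components, 15 exact neighbours and the Leiden method at resolution 1 (seed 1) on an unweighted neighbour graph, with no integration of libraries. A graph weighted by shared neighbours was dropped because it broke the cells into far more clusters. A cluster took a class name when at least 3 markers of the class were each detected in 50% of its cells, and was left unnamed when the share of another lineage reached 0.4. These naming limits and the graph were chosen after the values had been seen and before any test between groups.

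The test planned before the data were examined was a negative binomial test on summed counts. The deposited values are logs, so limma was used instead, although the recovered UMI counts would have allowed a count test, with the pseudocount and filter chosen after the values were seen and before any test. For each class and library, CPM were averaged over cells, and log2(CPM + 2) was fitted by group over all 13 libraries with limma's trend and robust options. Genes with a mean of at least 10 CPM were tested, and p-values were adjusted by Benjamini-Hochberg within a comparison at 0.05. A library needed 20 cells of the class, which left combination replicate 3 out for T-like cells. The added 2 CPM makes folds of weakly expressed genes too small. Adjusted p-values of genes in the text are limma's.

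Gene lists were fixed before the data were examined and tested by camera with a preset correlation of 0.01, adjusted over the lists of a class. Camera with an estimated correlation and fry were run beside it. Shares of classes were compared by exact permutation of libraries, adjusted over 10 classes, and the adjusted values of the other settings were added last. In 100 draws of data without a difference, 6 had a share p-value under 0.05, and 20 of 20 shifted draws did.

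Genes were named when among the 10 largest rises and falls with an adjusted p-value under 0.05, at least 20 CPM, no other class more than 10 times higher and groups whose libraries did not overlap, ribosomal, mitochondrial and unnamed genes aside. The antibody targets, the Fc receptors, up to 4 members of each list and the genes of the control pattern were named without these limits. Igfbp5, Tmsb10, Hbegf and Cd24a were named after their values were seen. Added after the calls were seen were the 10 genes with the smallest p-values that neither shared over 5% of the 50-base words of the first 500 bases of their transcripts with another gene nor moved alike in stromal cells. Alike meant a stromal log2 fold of at least 0.5 times the class value, tested where the stromal level was at least 0.25 times that of the class, and genes below that level were not left out. Coordinates are GRCm38, and 30411 genes were matched to the annotation by symbol. Monocyte-like cells were tested after the shares had been seen.

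On simulated data with 200 genes changed, the macrophage-like comparisons recovered from 81 to 92% of 2-fold and from 96 to 100% of 4-fold changes. Simulated libraries were drawn as independent, with no correlation between those that share a tag number. Epithelial-like comparisons recovered from 63 to 85% and from 96 to 99%, and T-like comparisons from 8 to 22% and from 44 to 59%.

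Other settings chosen in advance and run were the low-value filter, the cell filter (1000 UMIs, 500 genes, 8% mitochondrial UMIs), doublets, the macrophage class, the libraries in the fit, the instrument, the tag number and leaving out each library in turn. Added after the data were seen were pseudocounts of 0.5 and 10 CPM, median-ratio scaling, summed UMIs, a window of 5145 to 29730 UMIs and 1173 to 4974 genes that every library holds, the removal of genes with shared sequence, and values relative to the epithelial-like and stromal cells of the same library. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.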

Results

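The 13 libraries held 37456 cells of HER2-driven mammary tumours from mice given no antibody or an isotype antibody (control, 3 libraries), anti-CD47 (2), anti-HER2 (4) or anti-CD47 with anti-HER2 (combination, 4). After 1219 marked doublets were left out, 36237 cells remained, and 22 of the 50 clusters were named by markers. The named clusters formed macrophage-like, monocyte-like, neutrophil-like, T-like, epithelial-like, myoepithelial-like, fibroblast-like, endothelial-like and pericyte-like classes, and 5316 cells stayed unnamed. Macrophage-like cells numbered 137 to 894 per library.

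Monocyte-like cells made up 6.75 ± 2.69% of the cells of control libraries (mean ± SD, n = 3), 4.88 ± 0.336% with anti-CD47 (n = 2), 2.13 ± 0.25% with anti-HER2 (n = 4) and 1.56 ± 0.699% with the combination (n = 4). The 4 groups differed (exact permutation over 900900 assignments, p = 0.000258, adjusted p = 0.00258). With 1 value per tag number they did not pass (exact permutation over 630 assignments, p = 0.0476, adjusted p = 0.463). In that setting equal groups can trade labels without changing the test, so 1 class alone could not have passed after adjustment over classes. The group means there were 6.33, 4.88, 2.13 and 1.56%. Every control library lay above every anti-HER2 library and every combination library, each at an exact permutation p = 0.0286, the smallest value that 3 against 4 libraries can give, with adjusted p = 0.0952 for anti-HER2 and 0.143 for the combination. No difference passed for the combination against anti-HER2 (exact permutation p = 0.171) or for anti-CD47 against control (p = 0.6). The latter could not pass, as 2 against 3 libraries cannot give a value under 0.1.

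Epithelial-like cells made up 26.2 ± 17.0% of control, 27.8 ± 1.30% of anti-CD47, 42.9 ± 3.14% of anti-HER2 and 54.6 ± 17.8% of combination cells (exact permutation p = 0.0403, adjusted p = 0.201). Macrophage-like cells were 25.7 ± 10.4, 22.9 ± 6.39, 24.2 ± 4.78 and 15.9 ± 11.8% (exact permutation p = 0.428). T-like cells were 20.48 ± 24.2, 17.0 ± 20.1, 4.96 ± 4.52 and 1.39 ± 0.877% (exact permutation p = 0.142). Neutrophil-like cells, at 6.41, 3.33, 1.26 and 1.32%, also did not pass (exact permutation p = 0.115). Among the cells of the 4 named immune classes alone, macrophage-like cells were 49.1, 53.3, 74.6 and 75.9% (exact permutation p = 0.264) and monocyte-like cells 12.1, 10.9, 6.58 and 9.78% (p = 0.376). The shares of 4 classes in each library are shown with their means.

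**Figure D1:**
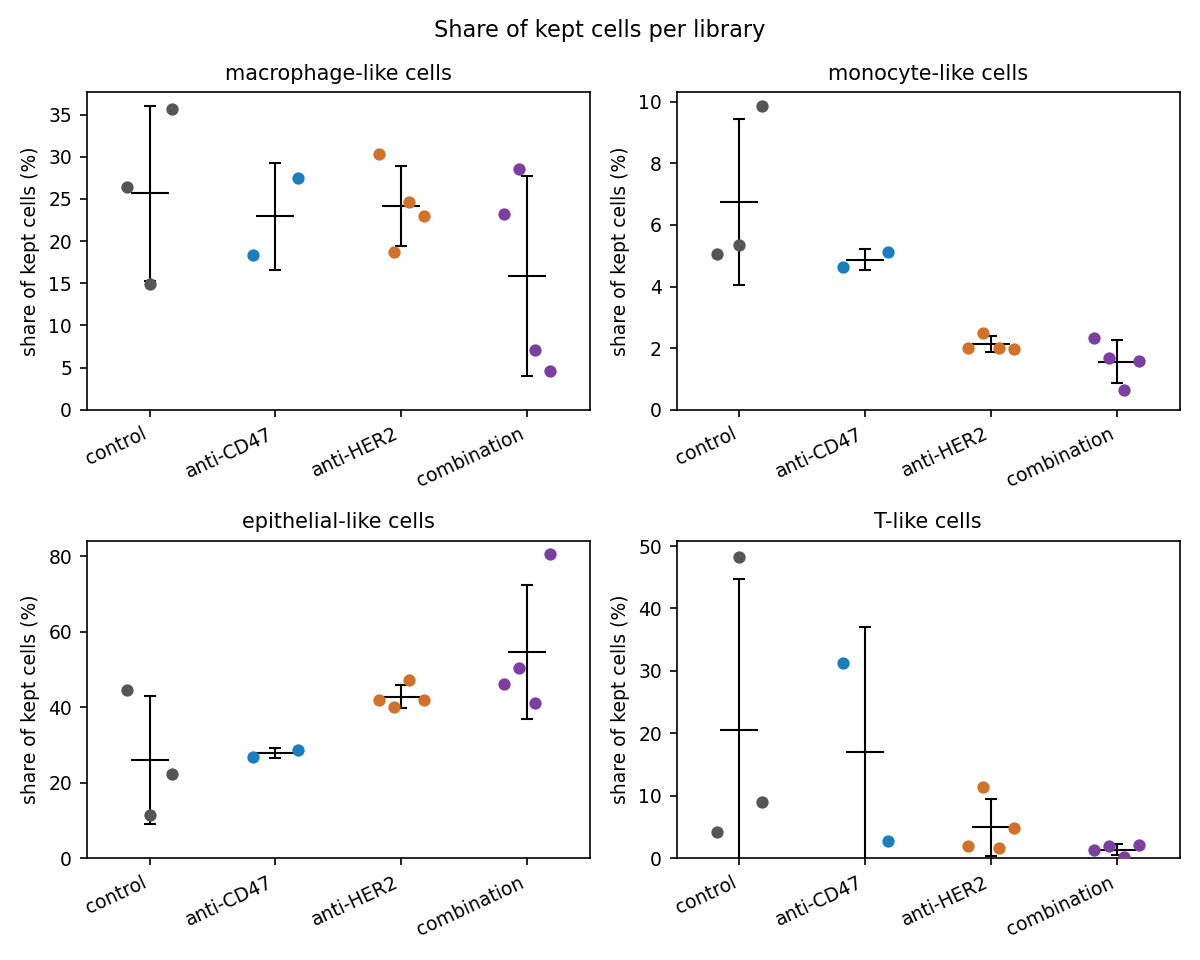
Shares of macrophage-like, monocyte-like, epithelial-like and T-like cells among the cells of each library, by treatment group. Points are libraries; the black tick and bars are the mean and SD.

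Ribosomal protein copies were among the largest changes of treated against control libraries, and the 3 comparisons rest on the same control libraries. In macrophage-like cells, the ribosomal protein copy Rpl9-ps6 (chromosome 19, 32465865 to 32466578) averaged 1624 CPM (counts scaled to the total of each cell) in control and 76.8, 72.2 and 74.9 CPM in anti-CD47, anti-HER2 and combination libraries. Its log2 folds against control were -4.37 ± 0.17, -4.46 ± 0.14 and -4.43 ± 0.14 (± SE; adjusted p = 1.45e-09, 9.41e-11 and 1.05e-10). Rnaset2a, a ribonuclease gene on chromosome 17 (8115445 to 8148097), fell from 547 CPM in control to 68.9, 81.4 and 78.5 CPM (adjusted p = 6.59e-05, 1.56e-05 and 1.69e-05). Rplp1, an acidic ribosomal stalk protein, had log2 folds of -2.77 ± 0.27, -2.40 ± 0.23 and -1.79 ± 0.23. Sh3bgrl3, a small thioredoxin-like protein on chromosome 4 (134127406 to 134128789), rose from 96.7 CPM to 657, 656 and 635 CPM (log2 fold 2.77 ± 0.17, 2.77 ± 0.14 and 2.72 ± 0.14).

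These genes moved by about as much in the stromal cells of the libraries. Log2 folds there were -4.02, -4.33 and -4.61 for Rpl9-ps6, -2.59, -2.69 and -2.41 for Rnaset2a, and 3.02, 2.94 and 2.72 for Sh3bgrl3. Of the genes called in macrophage-like cells, 46 of 68 for anti-CD47, 55 of 80 for anti-HER2 and 70 of 160 for the combination had a 5' end that shared over 5% of its sequence with another gene. The share was 67.6, 68.8 and 43.8%, against 15.9% of the genes not called for anti-CD47 and 15.8% for anti-HER2 (Fisher p = 3.8e-21, 1.32e-25 and 1.55e-16). Sh3bgrl3 itself shared 0%. The genes described below are therefore mostly those that neither shared such sequence nor were found to move alike in stromal cells, a selection made after the calls were seen. The stromal level was too low for this comparison for 11, 14 and 35 of the called genes, which were not left out for it.

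**Figure D2:**
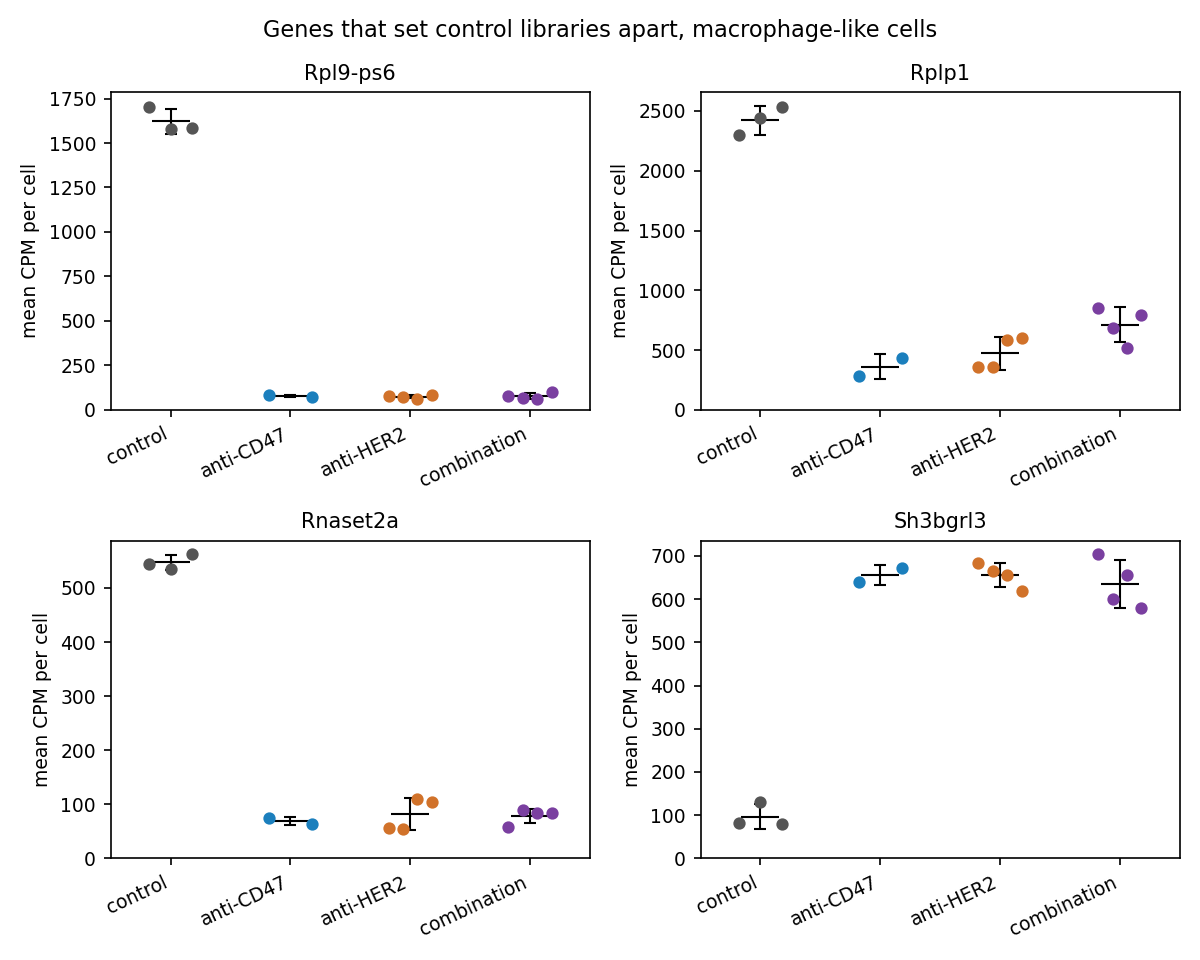
CPM of Rpl9-ps6, Rplp1, Rnaset2a and Sh3bgrl3 in the macrophage-like cells of each library. Points are libraries; the black tick and bars are the mean and SD.

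With anti-CD47, macrophage-like cells carried more Mpp7, a junction scaffold protein (chromosome 18, 7347959 to 7626866), at 47.2 CPM in 2 libraries against 19.8 CPM in 3 control libraries (log2 fold 1.18 ± 0.18, adjusted p = 0.00282). St3gal1, a sialyltransferase (chromosome 15, 67102875 to 67176830), rose from 31.1 to 63.9 CPM (0.99 ± 0.17, adjusted p = 0.00838). Acod1, the enzyme that makes itaconate (chromosome 14, 103046977 to 103056573), rose from 4.42 to 74.2 CPM (3.42 ± 0.48, adjusted p = 0.00469). Its level in neutrophil-like cells was 1402 CPM. Dusp2, a nuclear phosphatase of MAP kinases (chromosome 2, 127336159 to 127338376), fell from 206 to 105 CPM (-0.95 ± 0.17, adjusted p = 0.0136).

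Anxa1, an annexin that dampens inflammation (chromosome 19, 20373428 to 20390944), rose from 216 to 364 CPM (0.75 ± 0.16, adjusted p = 0.0429), and the zinc-finger transcription factor Klf6 from 359 to 605 CPM (0.75 ± 0.14, adjusted p = 0.0193). The secretory-pathway kinase Fam20c (0.96 ± 0.18, adjusted p = 0.0183), the phosphoinositide phosphatase Sacm1l (0.55 ± 0.11, adjusted p = 0.0336), the muscle-type adenylosuccinate synthase Adssl1 (0.98 ± 0.21, adjusted p = 0.0424) and Card19 (0.61 ± 0.13, adjusted p = 0.0424) also rose. Of the genes called, 14 rises and 1 fall neither shared sequence nor were found to move alike in stromal cells. In all, 45 genes rose and 23 fell among 7088 tested in macrophage-like cells with anti-CD47. The count was 32 without anti-CD47 replicate 1 and 40 without control replicate 3. Without anti-CD47 replicate 1, Mpp7 (adjusted p = 0.0962), St3gal1 (0.22), Fam20c (0.425), Klf6 (0.392), Anxa1, Card19, Sacm1l, Adssl1 and Dusp2 no longer passed. Of 21 such genes followed through every setting, 9 passed with each library left out in turn, Acod1 and 8 genes of the control pattern. Relative to the epithelial-like and stromal cells of the library 0 passed (552 genes at an unadjusted p under 0.05 in limma). With 1 value per tag number anti-CD47 was 1 value, so that setting cannot decide on these genes.

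Of 21 glycolysis and hypoxia genes in macrophage-like cells, 1 rose with anti-CD47 among all genes and 12 rose when adjusted over the list alone (median log2 fold 0.45). The gene that passed was Ankrd37, a hypoxia-induced ankyrin protein (0.97, adjusted p = 0.0183). The list was higher as a set (camera adjusted p = 4.60e-09; adjusted p = 0.596 with an estimated correlation). A cluster led by Gpnmb, Arg1 and Hmox1 held 31.3 and 26.2% of macrophage-like cells in anti-CD47 libraries and 6.0, 11.0 and 7.16% in control libraries, and the largest cluster 57.7 and 51.7% against 77.4, 74.3 and 78.9%. Of 10 MHC class II genes 1 fell, and 5 fell and 1 rose over the list alone (median -0.35; camera adjusted p = 0.000300, or adjusted p = 0.596 with an estimated correlation). The gene that fell, H2-DMb2, a peptide-loading chaperone chain, went from 541 to 235 CPM (-1.22 ± 0.23, adjusted p = 0.0183) and shares 10.3% of its 5' end with another gene.

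The 6 neutrophil markers had a median log2 fold of 2.18 in the macrophage-like cells of anti-CD47 libraries, with 0 past the limma test and 2 up over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.213 with an estimated correlation). Lipid-associated macrophage genes (19, median 0.33) and unfolded protein response genes (13, median 0.21) were each higher as a set (camera adjusted p = 0.0209 for each; adjusted p = 0.596 with an estimated correlation). The 76 ribosomal protein genes, a list without Rplp1 and the copies, had a median of -0.20 and a mean of -0.05. Of these, 7 rose and 0 fell, and camera called the set lower (adjusted p = 0.00149; adjusted p = 0.796 with an estimated correlation) while the fry test gave the other direction without passing (adjusted p = 0.741).

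With anti-HER2, Mpp7 rose to 56.1 CPM in 4 libraries against 19.8 CPM in 3 control libraries (log2 fold 1.42 ± 0.15, adjusted p = 5.05e-05) and passed under each of the 27 other settings and left-out libraries. Mpp7 also rose in T-like cells of these libraries, as given below. The check for like changes used stromal cells only. St3gal1 rose to 57.6 CPM (0.85 ± 0.14, adjusted p = 0.00561), and Gng12, a gamma subunit of G proteins (chromosome 6, 66896397 to 67021350), from 38.2 to 60.6 CPM (0.64 ± 0.11, adjusted p = 0.00879). Acod1 rose to 48.8 CPM (2.99 ± 0.41, adjusted p = 0.00294). Dusp2 fell to 126 CPM (-0.71 ± 0.15, adjusted p = 0.0278).

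The antisense transcript Bach2os (0.79 ± 0.14, adjusted p = 0.00876), Sacm1l (0.51 ± 0.09, adjusted p = 0.0124), Klf6 (0.62 ± 0.12, adjusted p = 0.0194), aminopeptidase N (Anpep, 0.72 ± 0.14, adjusted p = 0.0232), Anxa1 (0.63 ± 0.13, adjusted p = 0.0347), Fam20c (0.71 ± 0.15, adjusted p = 0.0367) and the mitochondrial sodium-calcium exchanger Slc8b1 (0.50 ± 0.11, adjusted p = 0.0408) also rose. The microtubule destabiliser Stmn1 rose as well (0.88 ± 0.18, adjusted p = 0.0258), with 22.6% of its 5' end shared. In macrophage-like cells of anti-HER2 libraries 55 genes rose and 25 fell against control. The count was 44 without control replicate 2 and 46 without control replicate 3. St3gal1 (adjusted p = 0.0503), Bach2os (0.0638) and Sacm1l (0.0833) no longer passed without control replicate 2, nor Gng12 (0.0622) and Sacm1l (0.0851) without control replicate 3. Of 27 genes followed through every setting, 11 passed with each library left out in turn, Mpp7, Acod1, the enolase Eno1 (-0.87, adjusted p = 0.00301) and 8 genes of the control pattern, 12 with 1 value per tag number and 1, Mpp7, relative to the epithelial-like and stromal cells.

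All 6 neutrophil markers were higher over the list alone in macrophage-like cells of anti-HER2 libraries (median 3.36), and 1 of them passed among all genes. That gene was G0s2, an inhibitor of triglyceride lipase (3.25 ± 0.61, adjusted p = 0.0336). This list passed with the preset correlation (camera adjusted p = 1.24e-08) and with an estimated one (adjusted p = 0.0489). Of 24 cell cycle genes 1 rose, and 2 rose over the list alone (median 0.24; camera adjusted p = 0.000321, or adjusted p = 0.475 with an estimated correlation).

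Of 10 MHC class II genes 1 rose and 1 fell with anti-HER2, and over the list alone 1 rose and 5 fell (median -0.26; camera adjusted p = 0.000352, or adjusted p = 0.475 with an estimated correlation). The pair of H2-DM beta chains parted: H2-DMb2 fell (-1.11 ± 0.19, adjusted p = 0.00876) and H2-DMb1 rose (0.62 ± 0.13, adjusted p = 0.036). The 5' end of H2-DMb2 shares sequence with another gene, as given above. Reads counted for another gene copy were not told apart from a change in expression. The 16 chemokine genes had a median of -0.26 with 0 past the limma test, and were lower as a set, as were 22 dissociation and heat shock genes (median -0.09), of which 1 rose (camera adjusted p = 0.0290 and 0.0222; adjusted p = 0.475 with an estimated correlation for each). Mitochondrially encoded genes (13, median 0.17, 3 up over the list alone) and unfolded protein response genes (13, median 0.18) were higher as sets (camera adjusted p = 0.0136 and 0.0290; adjusted p = 0.475 with an estimated correlation for each). Ribosomal protein genes had a median of -0.10 and a mean of 0.08, with 8 up and 1 down, and were called lower by camera (adjusted p = 0.0290; adjusted p = 0.721 with an estimated correlation), while fry gave the other direction without passing (adjusted p = 0.491).

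With the combination, Mki67, the nuclear protein of cycling cells (chromosome 7, 135689784 to 135716361), averaged 64.0 CPM in macrophage-like cells of 4 combination libraries and 31.5 CPM in 3 control libraries (log2 fold 1.01 ± 0.17, adjusted p = 0.00375). Stmn1 rose from 48.6 to 125 CPM (1.32 ± 0.18, adjusted p = 0.000849), the linker histone Hist1h1e by 1.25 ± 0.20 (adjusted p = 0.0027), the topoisomerase Top2a by 0.85 ± 0.18 (adjusted p = 0.022), the spindle factor Tpx2 by 0.73 ± 0.13 (adjusted p = 0.00784), the kinase subunit Cks1b by 0.61 ± 0.14 (adjusted p = 0.0362) and Hmgb2 by 0.48 ± 0.09 (adjusted p = 0.0108). Of 24 cell cycle genes 6 rose, 16 over the list alone, with a median of 0.51 (camera adjusted p = 6.69e-11; adjusted p = 0.129 with an estimated correlation). A cluster led by Birc5, Top2a and Mki67 held 14.9, 11.4, 11.5 and 8.76% of macrophage-like cells in combination libraries and 8.51, 8.36 and 6.94% in control libraries. Relative to the epithelial-like and stromal cells of the library, Mki67 (0.43, adjusted p = 0.535), Stmn1 (0.31, adjusted p = 0.555), Top2a (0.06, adjusted p = 0.933), Tpx2 (-0.08, adjusted p = 0.911) and Hist1h1e (1.04, adjusted p = 0.0577) did not pass. With 1 value per tag number Hist1h1e passed (adjusted p = 0.0142), and Mki67 (0.235), Stmn1 (0.123), Top2a (0.257) and Tpx2 (0.211) did not.

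The lysosomal thioesterase Ppt1 (chromosome 4, 122836242 to 122859175) fell from 214 to 147 CPM in macrophage-like cells with the combination (-0.54 ± 0.09, adjusted p = 0.00449). Complement C1qa (chromosome 4, 136895917 to 136898803) fell by 0.48 ± 0.09 (adjusted p = 0.01), C1qb by 0.33 ± 0.07 (adjusted p = 0.0203), Apoe by 0.55 ± 0.11 (adjusted p = 0.0121) and the high-affinity IgG receptor Fcgr1 by 0.43 ± 0.10 (adjusted p = 0.0326). C1qa, C1qb, C1qc, Apoe and Fcgr1 are among the markers that named the class, and the C1q genes, Apoe, Cd74, H2-Ab1 and H2-Aa lead its largest cluster. That cluster held 77.4, 74.3 and 78.9% of macrophage-like cells in control and 60.4, 74.3, 45.5 and 64.2% in combination libraries.

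Of 10 MHC class II genes 5 fell with the combination, 6 over the list alone with 1 up (median -0.39; camera adjusted p = 1.02e-06, or adjusted p = 0.25 with an estimated correlation). H2-Ab1, a class II beta chain (chromosome 17, 34257689 to 34269419), fell from 10165 to 6537 CPM (-0.65 ± 0.12, adjusted p = 0.0105), H2-Aa by 0.51 ± 0.11 (adjusted p = 0.0225), the invariant chain Cd74 by 0.63 ± 0.13 (adjusted p = 0.0223) and H2-DMb2 by 1.42 ± 0.19 (adjusted p = 0.000849). The limit on H2-DMb2 from shared sequence applies here too. Relative to the epithelial-like and stromal cells, Cd74 (0.04, adjusted p = 0.992), H2-Ab1 (-0.30, adjusted p = 0.901) and H2-Aa (-0.30, adjusted p = 0.918) did not pass. Of 33 lysosome genes 3 fell and 1 rose, 9 down and 1 up over the list alone (median -0.15; camera adjusted p = 1.02e-06, or adjusted p = 0.29 with an estimated correlation), among them the cathepsins Ctsz (-0.37 ± 0.08, adjusted p = 0.0348) and Ctsh (-0.34 ± 0.08, adjusted p = 0.0469). Of 10 complement genes 3 fell (median -0.28; camera adjusted p = 0.00018, or adjusted p = 0.192 with an estimated correlation). Of 28 Fc receptor and phagocytosis genes 2 fell, Fcgr1 among them, with a median of -0.08 (camera adjusted p = 0.00898; adjusted p = 0.192 with an estimated correlation).

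Several other genes changed against control. Mpp7 (1.46 ± 0.15, adjusted p = 3.95e-05), Gng12 (0.74 ± 0.11, adjusted p = 0.00219), St3gal1 (0.93 ± 0.14, adjusted p = 0.00219), Sacm1l (0.56 ± 0.09, adjusted p = 0.00497), the helicase Dhx40 (0.64 ± 0.13, adjusted p = 0.0193), Anpep (0.68 ± 0.14, adjusted p = 0.0231), the glutathione transferase Mgst1 (0.90 ± 0.20, adjusted p = 0.0382), the fatty acid desaturase Scd2 (1.32 ± 0.23, adjusted p = 0.00599) and Acod1 (2.94 ± 0.41, adjusted p = 0.0027) rose. Eepd1 (-0.67 ± 0.12, adjusted p = 0.00834), the nucleotidase Nt5c (-0.48 ± 0.09, adjusted p = 0.0102), the adaptor Scimp (-0.64 ± 0.13, adjusted p = 0.0168) and the lysosomal nuclease Dnase2a (-0.50 ± 0.10, adjusted p = 0.0198) fell. The epithelial protease inhibitor Spint2 rose from 3.95 to 25.2 CPM (2.09 ± 0.32, adjusted p = 0.00277). The 6 neutrophil markers had a median of 1.61, with 0 past the limma test and 4 up over the list alone (camera adjusted p = 0.000613; adjusted p = 0.192 with an estimated correlation).

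Sets called higher with the combination were inflammatory and NF-kB genes (21, median 0.28, 1 up; camera adjusted p = 0.0132), glycolysis and hypoxia genes (21, median 0.25, 3 up and 1 down; camera adjusted p = 0.00898), mitochondrially encoded genes (13, median 0.26, 2 up; camera adjusted p = 1.02e-05) and ribosomal protein genes (76, median 0.14, 10 up; camera adjusted p = 1.20e-07). With an estimated correlation these lists had adjusted p = 0.716, 0.716, 0.29 and 0.491. In macrophage-like cells of combination libraries 101 genes rose and 59 fell against control, and the count was 71 without control replicate 2 and 72 without control replicate 3. Mpp7, Gng12, St3gal1, Mki67, Stmn1, Sacm1l, Acod1, Ppt1, H2-DMb2 and Spint2 passed with each library left out in turn. Of 40 genes followed through every setting, 11 passed with 1 value per tag number and 3 relative to the epithelial-like and stromal cells. Without control replicate 3 the values of C1qa (adjusted p = 0.084), C1qb (0.146), H2-Ab1 (0.0835), H2-Aa (0.14), Cd74 (0.127), Apoe (0.084) and Top2a (0.084) did not pass, and without control replicate 2 neither did those of Tpx2 (0.0601), Hmgb2 (0.0697), Dhx40 (0.108) and Eepd1 (0.0697).

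**Figure D3:**
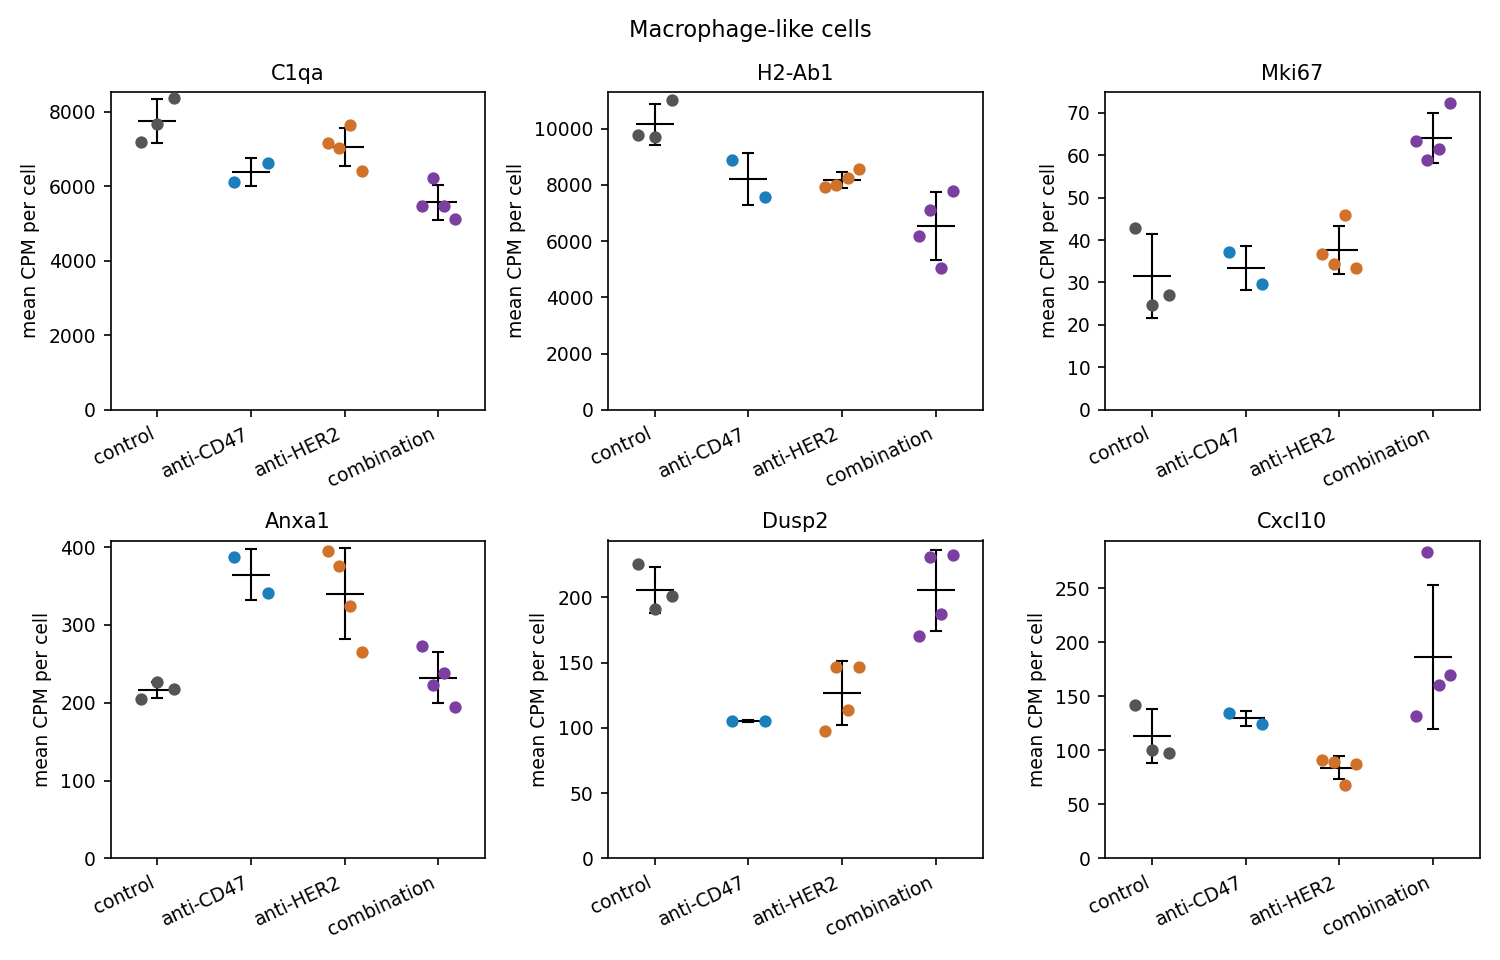
CPM of C1qa, H2-Ab1, Mki67, Anxa1, Dusp2 and Cxcl10 in the macrophage-like cells of each library. Points are libraries; the black tick and bars are the mean and SD.

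Against anti-HER2 alone, combination macrophage-like cells carried more Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889), at 186 against 84.0 CPM with 4 libraries in each group (log2 fold 1.08 ± 0.20, adjusted p = 0.0445). Dusp2 was also higher, at 205 against 126 CPM (0.70 ± 0.14, adjusted p = 0.0445). Pianp, a ligand of the paired receptor PILR alpha (chromosome 6, 124996694 to 125003096), fell from 94.4 to 65.4 CPM (-0.52 ± 0.07, adjusted p = 0.00807). The common cytokine receptor chain Il2rg (-0.55 ± 0.10, adjusted p = 0.0284), the lysosomal membrane protein Gpr137b (-0.70 ± 0.11, adjusted p = 0.0189), the read-through transcript Tnfsfm13 (-0.56 ± 0.10, adjusted p = 0.0272), the antiviral synthetase Oas1a (-0.60 ± 0.08, adjusted p = 0.00792) and C1qb (-0.33 ± 0.06, adjusted p = 0.0445) fell. Relative to the epithelial-like and stromal cells, Oas1a turned direction (0.23, adjusted p = 0.612).

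The genes that rose included 12 that were more than 2 times higher in epithelial-like than in macrophage-like cells. Among them were the acyl-CoA binding protein Dbi, from 257 to 376 CPM (0.54 ± 0.10, adjusted p = 0.0374), and Spint2, from 4.54 to 25.2 CPM (1.98 ± 0.30, adjusted p = 0.0116). In this comparison 16 genes rose and 7 fell in macrophage-like cells. The count was 74 without combination replicate 1 and 41 without combination replicate 4, and 11, 14, 12 and 11 without anti-HER2 replicates 1, 2 and 3 and combination replicate 2. Pianp, Oas1a and Spint2 passed with each library left out in turn, and limma called 0 genes with 1 value per tag number (430 at an unadjusted p under 0.05). Of 10 genes followed through every setting, none passed relative to the epithelial-like and stromal cells (862 genes at an unadjusted p under 0.05 in limma), where Dbi turned direction (-0.31, adjusted p = 0.603).

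Of 16 chemokine genes 1 rose in combination against anti-HER2 macrophage-like cells (median 0.68; camera adjusted p = 0.000169, or adjusted p = 0.169 with an estimated correlation). Lysosome genes (33) had a median of -0.22, with 0 past the limma test and 13 down over the list alone (camera adjusted p = 4.27e-11; adjusted p = 0.169 with an estimated correlation). Fc receptor and phagocytosis genes (28) had a median of -0.14, with 6 down over the list alone (camera adjusted p = 0.000765; adjusted p = 0.169 with an estimated correlation). Of 28 type I interferon genes 1 fell, Oas1a, with a median of -0.28 (camera adjusted p = 0.000362; adjusted p = 0.464 with an estimated correlation). Ribosomal protein genes (median 0.24, 17 up over the list alone) and cell cycle genes (median 0.23, 4 up over the list alone) were higher as sets (camera adjusted p = 1.82e-21 and 7.59e-06; adjusted p = 0.169 with an estimated correlation for each).

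Inflammatory and NF-kB genes (median 0.26; camera adjusted p = 8.62e-06), glycolysis and hypoxia genes (0.00367) and mitochondrially encoded genes (0.0104) were also higher as sets in this comparison. MHC class II (0.00528), complement (0.00594), lipid-associated macrophage genes (0.0374) and neutrophil markers (median -0.99; 0.0205) were lower as sets. With an estimated correlation their adjusted p was 0.405, 0.464, 0.464, 0.464, 0.303, 0.464 and 0.367 in that order.

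Against anti-CD47 alone (2 libraries), combination macrophage-like cells had more Dusp2 (log2 fold 0.94 ± 0.17, adjusted p = 0.0453), Hist1h1e (1.23 ± 0.22, adjusted p = 0.0482), the acyl-CoA synthetase Acsl3 (0.84 ± 0.15, adjusted p = 0.0453), the small nucleolar ribonucleoprotein Nop10 (0.70 ± 0.12, adjusted p = 0.0439) and Spint2 (2.62 ± 0.36, adjusted p = 0.0207). Oas1a was lower (-0.67 ± 0.10, adjusted p = 0.0207), but turned direction relative to the epithelial-like and stromal cells (0.57, adjusted p = 0.335). Of 24 cell cycle genes 0 passed the limma test and 14 rose over the list alone (median 0.47; camera adjusted p = 1.60e-10, or adjusted p = 0.154 with an estimated correlation). Ribosomal protein genes (median 0.36, 46 up over the list alone) were higher and lysosome genes (median -0.28, 7 down over the list alone) lower as sets (camera adjusted p = 8.75e-20 and 3.61e-10; adjusted p = 0.282 with an estimated correlation for each).

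Glycolysis and hypoxia (camera adjusted p = 0.000249), lipid-associated (0.00321), complement (0.00439), Fc receptor and phagocytosis (0.0253), type I interferon (0.0263) and alternative activation genes (0.0273) were lower as sets and mitochondrially encoded genes (0.0263) higher. With an estimated correlation their adjusted p was 0.474, 0.411, 0.283, 0.282, 0.626, 0.474 and 0.562. In this comparison 10 genes rose and 1 fell, against 985 genes at an unadjusted p under 0.05. The count was 0 without anti-CD47 replicate 1 (446 at an unadjusted p under 0.05 in limma), 3 without anti-CD47 replicate 2 and 22 without combination replicate 4. It was 6 without anti-HER2 replicate 3 or combination replicate 2 and 7 without control replicate 2 or 3. None of the 6 genes named passed with each library left out in turn, and 1, Spint2, passed relative to the epithelial-like and stromal cells (adjusted p = 0.0262). With 1 value per tag number anti-CD47 was 1 value, so that setting cannot decide on these genes.

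The effect of adding anti-CD47 differed with and without anti-HER2 for 73 genes in macrophage-like cells, 30 up and 43 down in the test of (combination - anti-HER2) - (anti-CD47 - control). Of these, 43 share sequence with another gene, so the control pattern is counted in them again. A rise alike in all treated groups passes too, as for Mpp7 and Acod1. Dusp2 fell with anti-CD47 alone and rose when it was added to anti-HER2 (difference 1.65 ± 0.22, adjusted p = 0.00105). Of 12 genes followed, 0 passed relative to the epithelial-like and stromal cells (797 genes at an unadjusted p under 0.05 in limma). With 1 value per tag number anti-CD47 was 1 value, which cannot decide. Anxa1 averaged 216, 364, 340 and 232 CPM in control, anti-CD47, anti-HER2 and combination libraries (difference -1.29 ± 0.20, adjusted p = 0.00462). Fam20c averaged 46.5, 92.5, 78.2 and 59.1 CPM (-1.33 ± 0.23, adjusted p = 0.0107), and Klf6 359, 605, 551 and 501 CPM (-0.90 ± 0.18, adjusted p = 0.0294).

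The sterol-sensing receptor Nr1h3 averaged 12.9, 25.9, 25.6 and 13.0 CPM (-1.85 ± 0.34, adjusted p = 0.016). The fractalkine receptor Cx3cr1, at 394, 253, 327 and 389 CPM (0.88 ± 0.18, adjusted p = 0.0292), and Myc (0.88 ± 0.19, adjusted p = 0.0365) went the other way, though Cx3cr1 turned direction relative to the epithelial-like and stromal cells (-0.20, adjusted p = 0.936). Mpp7 (-1.14 ± 0.22, adjusted p = 0.0263), the calcium sensor Hpcal1 (-0.74 ± 0.15, adjusted p = 0.0277), the sphingosine kinase Sphk2 (-0.80 ± 0.18, adjusted p = 0.0452), Acod1 (-3.47 ± 0.61, adjusted p = 0.0232) and the antisense transcript Epb41l4aos (0.88 ± 0.17, adjusted p = 0.0205) also passed. The count was 36 without anti-CD47 replicate 1 and 46 without control replicate 2. Of these 12 genes only Dusp2 passed with each library left out in turn. Anxa1 (adjusted p = 0.0517), Fam20c (0.109), Mpp7 (0.238), Klf6 (0.254), Cx3cr1 (0.124), Myc (0.118), Hpcal1 (0.152) and Acod1 (0.0902) did not pass without anti-CD47 replicate 1, nor Nr1h3 (0.0535), Epb41l4aos (0.0535) and Sphk2 (0.11) without control replicate 2. By list, 6 neutrophil markers had a median difference of -3.35, with 0 past the limma test and 6 down over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.215 with an estimated correlation), and lysosome genes a median of -0.28 with 10 down over the list alone (camera adjusted p = 4.81e-06; adjusted p = 0.47 with an estimated correlation).

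Ribosomal protein genes had a median difference of 0.45, with 2 up and 6 down among all genes and 39 up over the list alone (camera adjusted p = 7.23e-12; adjusted p = 0.47 with an estimated correlation). Type I interferon (camera adjusted p = 0.00748), lipid-associated (0.00322), glycolysis and hypoxia (0.0099) and unfolded protein response genes (0.0144) were lower as sets, and interferon gamma response (0.041), cell cycle (0.0144) and dissociation and heat shock genes (0.0289) higher. With an estimated correlation their adjusted p was 0.664, 0.47, 0.65, 0.499, 0.472, 0.499 and 0.65.

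In macrophage-like cells Cd47, the target of the first antibody (chromosome 16, 49800533 to 49915010), averaged 209, 244, 253 and 211 CPM in control, anti-CD47, anti-HER2 and combination libraries, and its receptor Sirpa 285, 297, 309 and 282 CPM. The inhibitory Fc receptor Fcgr2b averaged 786, 1050, 935 and 652 CPM, Fcgr3 805, 779, 752 and 632 CPM, and Fcgr4, a receptor for IgG2a, 91.4, 78.9, 98.0 and 54.3 CPM. Of these, none passed, while Fcgr1 fell with the combination as given above. Fcgr4 came nearest, at -0.84 ± 0.17 for the combination against anti-HER2 (adjusted p = 0.054) and -0.72 ± 0.18 against control (adjusted p = 0.0563).

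In epithelial-like cells the human ERBB2 transgene averaged 278 ± 93 CPM in control, 188 ± 56 with anti-CD47, 260 ± 43 with anti-HER2 and 428 ± 121 with the combination (mean ± SD), and passed in no comparison (combination against control 0.62 ± 0.27, adjusted p = 0.228). Mouse Erbb2 (chromosome 11, 98412470 to 98437716), the endogenous counterpart, averaged 25.9, 37.4, 41.6 and 53.1 CPM and rose with the combination against control (0.99 ± 0.16, adjusted p = 0.00465), but not with anti-HER2 (0.66 ± 0.16, adjusted p = 0.124). Cd47 averaged 88.2, 136, 102 and 96.3 CPM in these cells and did not pass.

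With anti-CD47, epithelial-like cells carried less Pde9a, a cyclic GMP phosphodiesterase (chromosome 17, 31386210 to 31476310), at 13.9 CPM in 2 libraries against 25.4 CPM in 3 control libraries (log2 fold -0.78 ± 0.14, adjusted p = 0.0282). The heterochromatin protein Hp1bp3 (-0.84 ± 0.17, adjusted p = 0.0408), Rsbn1l (-0.91 ± 0.18, adjusted p = 0.046) and the oxysterol-binding protein Osbpl7 (-0.90 ± 0.18, adjusted p = 0.046) also fell. Usp50, a ubiquitin protease relative (chromosome 2, 126709096 to 126783470), rose from 4.6 to 93.2 CPM (3.91 ± 0.42, adjusted p = 0.000545), as it did in stromal cells (4.14), and Sh3bgrl3 (2.05 ± 0.30) and Rpl9-ps6 (-3.85 ± 0.23) moved as in macrophage-like cells. In all, 21 genes rose and 21 fell among 8007 tested in epithelial-like cells with anti-CD47, and 69.0% of them share sequence. The count was 18 without anti-CD47 replicate 1, 25 without control replicate 3, 72 without control replicate 1 and 75 without combination replicate 1. Usp50, Sh3bgrl3 and Rpl9-ps6 passed with each library left out in turn, and Pde9a, Hp1bp3, Rsbn1l and Osbpl7 did not. With 1 value per tag number anti-CD47 was 1 value, so that setting cannot decide on these genes.

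Interferon gamma response genes (14) had a median of 0.77 with anti-CD47 in epithelial-like cells, with 0 past the limma test and 2 up over the list alone (camera adjusted p = 0.000164; adjusted p = 0.562 with an estimated correlation). MHC class I genes (16, median 0.33) and p53 and apoptosis genes (15, median 0.33) were also higher as sets (camera adjusted p = 0.00272 for each; adjusted p = 0.562 with an estimated correlation for each). Ribosomal protein genes were called higher (camera adjusted p = 0.00574; adjusted p = 0.573 with an estimated correlation) with 8 up, a mean of 0.09 and a median of -0.03. Mesenchymal transition (camera adjusted p = 0.0141), chemokine (0.0161), dissociation and heat shock (0.0191), unfolded protein response (0.0195), type I interferon (0.0195) and cell cycle genes (0.0468) were higher as sets, with 0 past the limma test (1213 genes at an unadjusted p under 0.05 in all). With an estimated correlation the adjusted p was 0.562 for the first 4 and 0.6 for the last pair.

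With anti-HER2, 22 genes rose and 21 fell in epithelial-like cells against control, and 81.4% of them share sequence with another gene. Usp50 rose to 124 CPM (log2 fold 4.27 ± 0.36, adjusted p = 3.91e-05), with Sh3bgrl3 (2.44 ± 0.25) and the syntaxin Stx16 (0.97 ± 0.13). Rpl9-ps6 (-4.18 ± 0.19), the glutathione synthesis subunit Gclm (-1.03 ± 0.15, adjusted p = 0.00296) and the histone deacetylase Hdac1 (-1.01 ± 0.13, adjusted p = 0.00124) fell. Of the called genes, 0 were free of shared sequence and of a like change in stromal cells (43 called by limma, 736 at an unadjusted p under 0.05). Dissociation and heat shock genes (22) had a median of 0.37, with 0 past the limma test and 1 up over the list alone (camera adjusted p = 3.03e-10). Mitochondrially encoded (13, median 0.23; 5.90e-07), ERK output (20, median 0.15; 0.000274) and chemokine genes (6, median 0.52; 0.0148) were higher as sets too. Each of these 4 lists had adjusted p = 0.174 with an estimated correlation. So were p53 and apoptosis (camera adjusted p = 0.0269) and unfolded protein response genes (0.0325), each with adjusted p = 0.635 with an estimated correlation.

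With the combination, epithelial-like cells carried less Apoc1, an apolipoprotein (chromosome 7, 19689481 to 19692660), at 5.46 CPM in 4 libraries against 121 CPM in 3 control libraries (log2 fold -4.12 ± 0.48, adjusted p = 0.00108). The aryl hydrocarbon receptor Ahr (-1.18 ± 0.20, adjusted p = 0.0115), Luzp1 (-1.11 ± 0.20, adjusted p = 0.0125), the mucin Muc1 (-1.11 ± 0.23, adjusted p = 0.036), Pde9a (-0.64 ± 0.12, adjusted p = 0.0218) and the stem cell antigen Ly6a (-4.81 ± 0.88, adjusted p = 0.0343) fell. So did the ribosome assembly factor Ppan (-0.65 ± 0.12, adjusted p = 0.0216), the splicing factor Srsf4 (-0.77 ± 0.15, adjusted p = 0.0301), Eva1b (-0.91 ± 0.18, adjusted p = 0.0301), Rps19bp1 (-0.63 ± 0.13, adjusted p = 0.0341) and Grrp1 (-1.54 ± 0.32, adjusted p = 0.0424). Besides Erbb2, Top2a (1.17 ± 0.24, adjusted p = 0.0333), Stmn1 (1.15 ± 0.21, adjusted p = 0.021) and Tmem256 (0.81 ± 0.17, adjusted p = 0.0343) rose.

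Of 22 type I interferon genes 2 fell in epithelial-like cells of combination against control libraries and 10 over the list alone (median -0.91; camera adjusted p = 2.95e-08, or adjusted p = 0.472 with an estimated correlation). Isg15, a ubiquitin-like interferon product (chromosome 4, 156199424 to 156200818), went from 423 to 133 CPM (-1.65 ± 0.34, adjusted p = 0.0481). The 16 MHC class I genes had a median of -0.69, with 0 past the limma test and 10 down over the list alone, and 2 of 22 cell cycle genes rose, with a median of 0.46 (camera adjusted p = 2.98e-05 and 3.65e-07; adjusted p = 0.472 with an estimated correlation for each). Mitochondrially encoded genes had 1 up and 11 up over the list alone (median 0.44; camera adjusted p = 4.28e-09, or adjusted p = 0.28 with an estimated correlation), and ribosomal protein genes 10 up (median 0.04; camera adjusted p = 2.73e-05, or adjusted p = 0.472 with an estimated correlation). Interferon gamma response (median -0.68; camera adjusted p = 0.00946) and milk and luminal genes (median -0.78; 0.0353) were lower as sets and glycolysis and hypoxia genes (median 0.40; 0.0116) higher. Dissociation and heat shock, p53 and apoptosis, and mesenchymal transition genes were lower and ERK output and unfolded protein response genes higher, each at a camera adjusted p = 0.0478. All 8 of these lists had adjusted p = 0.472 with an estimated correlation.

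In this comparison 34 genes rose and 45 fell in epithelial-like cells. The count was 1067 without combination replicate 1, 276 without control replicate 1, 49 and 45 without combination replicates 3 and 4, and 43 and 39 without control replicates 2 and 3. Erbb2 and Apoc1 passed with each library left out in turn, as did Usp50 (3.49 ± 0.36), Sh3bgrl3 (1.90 ± 0.25) and Rpl9-ps6 (-4.10 ± 0.19), while Ahr (adjusted p = 0.0905) and Luzp1 (0.1) did not pass without control replicate 2, nor Pde9a (0.152) without control replicate 3. Of 19 genes followed through every setting, 6 passed with 1 value per tag number. In combination replicates 2 to 4, 4.22, 4.19 and 2.3% of epithelial-like cells lay in the cluster that held 34.5 to 66.1% of them in each of the other libraries.

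Against anti-HER2 alone, combination epithelial-like cells had less Pde9a, at 15.5 against 32.7 CPM with 4 libraries in each group (log2 fold -0.99 ± 0.11, adjusted p = 0.00431). Dusp1, a MAP kinase phosphatase (chromosome 17, 26505590 to 26562128), fell from 974 to 346 CPM (-1.52 ± 0.23, adjusted p = 0.0395), the transcription factor Klf2 from 503 to 214 CPM (-1.24 ± 0.20, adjusted p = 0.0395), and the heat shock protein Dnajb1 (-0.92 ± 0.15, adjusted p = 0.0395) and Trim47 (-0.76 ± 0.13, adjusted p = 0.0478) also fell. The kinase anchor Akap11 (0.95 ± 0.16, adjusted p = 0.0478) and the ciliary protein Cep290 (0.57 ± 0.09, adjusted p = 0.0395) rose. Of 22 dissociation and heat shock genes 2 fell and 13 over the list alone (median -0.58; camera adjusted p = 2.01e-10, or adjusted p = 0.229 with an estimated correlation).

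The 22 type I interferon genes had a median of -0.80, with 0 past the limma test and 11 down over the list alone, and the 16 MHC class I genes a median of -0.65 with 8 down over the list alone (camera adjusted p = 6.31e-10 and 4.53e-06). Cell cycle genes had a median of 0.56 with 9 up over the list alone (camera adjusted p = 9.09e-06). These 3 lists had adjusted p = 0.328 with an estimated correlation. Milk and luminal genes were lower (median -0.57, mean -1.43; camera adjusted p = 0.00052, or adjusted p = 0.321 with an estimated correlation), with 8 down and 2 up over the list alone. Interferon gamma response (median -0.88; camera adjusted p = 7.59e-05), p53 and apoptosis (median -0.58; 0.000303) and mesenchymal transition genes (median -1.08; 0.0013) were lower as sets. Glycolysis and hypoxia (median 0.37; 0.0013), ribosomal protein (median 0.16; 0.000303) and mitochondrially encoded genes (median 0.18; 0.00382) were higher. With an estimated correlation the adjusted p was 0.374 for ribosomal protein genes and 0.328 for the other 5 lists. In this comparison 2 genes rose and 5 fell, against 1907 genes at an unadjusted p under 0.05. The count was 1496 without combination replicate 1, 21 without control replicate 1, 3 without control replicate 3, 2 without combination replicate 3 and 1 without any other library. Pde9a passed with each library left out in turn, but not with 1 value per tag number (adjusted p = 0.244) or on 1 instrument, where the combination was 1 library (-1.04, adjusted p = 0.306).

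**Figure D4:**
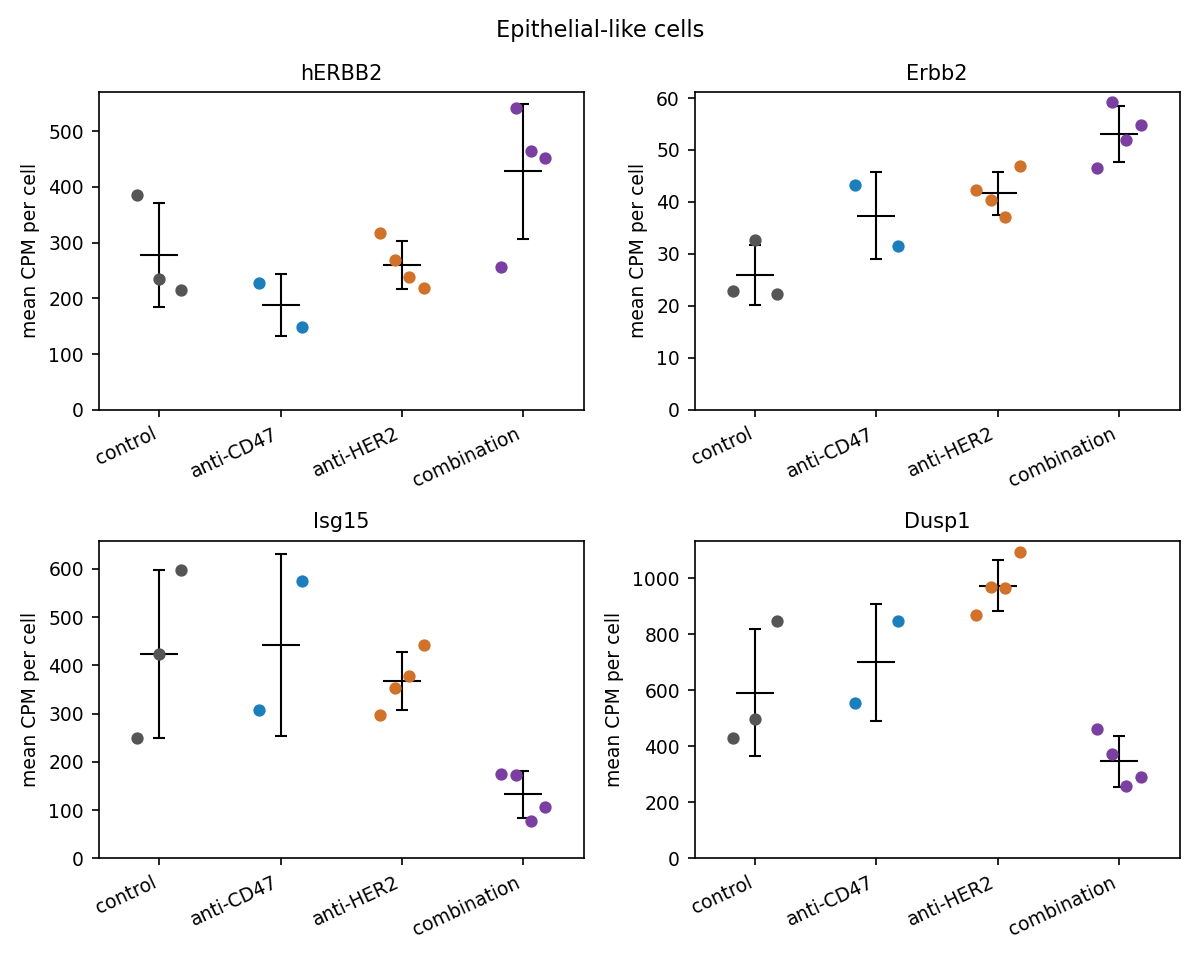
CPM of human ERBB2, mouse Erbb2, Isg15 and Dusp1 in the epithelial-like cells of each library. Points are libraries; the black tick and bars are the mean and SD.

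In T-like cells Cd69, an early activation antigen (chromosome 6, 129267325 to 129275436), averaged 704 CPM in 4 anti-HER2 libraries against 290 CPM in 3 control libraries (log2 fold 1.33 ± 0.22, adjusted p = 0.00393). The AP-1 subunits Fos (chromosome 12, 85473890 to 85477273), from 317 to 704 CPM (1.14 ± 0.17, adjusted p = 0.00122), and Jun, from 169 to 521 CPM (1.64 ± 0.27, adjusted p = 0.0052), rose as well. Mpp7 rose from 14.1 to 69.5 CPM (2.12 ± 0.31, adjusted p = 0.00111). These 4 genes passed with each library left out in turn but not with 1 value per tag number, where the adjusted p was 0.118 for Cd69, 0.115 for Fos, 0.209 for Jun and 0.0537 for Mpp7.

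In T-like cells 25 genes rose and 12 fell among 7173 tested with anti-HER2, 78.4% of them with shared sequence, Sh3bgrl3 (2.94 ± 0.19) and Rpl9-ps6 (-4.36 ± 0.25) included. Of 22 dissociation and heat shock genes 2 rose, 4 over the list alone (median 0.12), and 29 cell cycle genes had a median of 0.48 with 0 past the limma test (camera adjusted p = 0.0126 and 0.000285; adjusted p = 0.985 with an estimated correlation for each). Mitochondrially encoded genes (median 0.20) were higher as a set too (camera adjusted p = 0.00603; adjusted p = 0.985 with an estimated correlation). The T-like cells held naive, regulatory and Il17a-expressing clusters whose parts differed widely between libraries.

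With the combination, 21 genes rose and 9 fell in T-like cells against control, from 3 combination libraries because replicate 3 held 17 such cells, and 80.0% of them share sequence. The nucleoside transporter Slc29a1 (1.62 ± 0.34, adjusted p = 0.0462) and the condensin subunit Ncapd2 (1.70 ± 0.36, adjusted p = 0.0469) rose. The tetraspanin Tspan32 fell (-1.68 ± 0.29, adjusted p = 0.00964). Without control replicate 2, Slc29a1 (adjusted p = 0.225), Ncapd2 (0.278) and Tspan32 (0.0848) did not pass. The 29 cell cycle genes had a median of 1.06 and 10 naive and memory genes one of -1.07, with 0 past the limma test (536 genes at an unadjusted p under 0.05 in all) or over either list alone (camera adjusted p = 2.84e-11 and 6.11e-05; adjusted p = 0.74 with an estimated correlation for each). The 8 epithelial markers had a median of 1.54 and 24 type I interferon genes one of 0.55 in these cells (camera adjusted p = 0.0154 and 0.00201; adjusted p = 0.74 with an estimated correlation for each). The count of genes was 19 without combination replicate 1.

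Against anti-HER2, 1 gene rose in combination T-like cells, with 501 at an unadjusted p under 0.05. It was the predicted gene Gm10073, at 838 against 101 CPM (log2 fold 3.01 ± 0.21, adjusted p = 7.69e-07), named here after its value was seen. The count was 2 without anti-HER2 replicate 2 or combination replicate 2 and 18 without combination replicate 4. Type I interferon genes (median 0.69) and cell cycle genes (median 0.46) were higher and naive and memory genes (median -0.87) lower as sets (camera adjusted p = 2.67e-05, 3.22e-05 and 2.67e-05; adjusted p = 0.798, 0.798 and 0.793 with an estimated correlation). The 8 epithelial markers (median 1.69) were higher and mitochondrially encoded genes (median -0.20) lower as sets (camera adjusted p = 0.000357 and 0.00461; adjusted p = 0.798 with an estimated correlation for each).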

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

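The tests of gene copies, of RNA from epithelial-like cells and of the instrument were chosen after the results they test had been seen. Chance puts 1 library this far from the rest in about 1 in 20 groups, and 21 of the 243 groups tested had such a library.

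Combination replicate 3 held 9156 cells against 2270 to 3040 in the rest of its group, and 43.3% of its kept cells lay in unnamed clusters against 3.99 to 4.62% in its group and 5.87 to 6.86% in control libraries. The labels give 4000 to 6000 sorted cells per reaction. Unnamed clusters that came mostly from this library held markers of more than 1 lineage. The largest had 1196 cells, 89.2% from this library, with macrophage and epithelial markers and 12.1% marked doublets. The library stayed in the combination shares. Epithelial-like cells were 54.6% of kept combination cells and 64.4% of those in named classes. Anti-HER2 replicate 4 had a median of 12895 UMIs per cell against 19052 to 19545. Monocyte-like cells were 2.51% in anti-HER2 replicate 2 against 1.99 to 2.02%, and myoepithelial-like cells 6.44% in anti-HER2 replicate 3 against 1.88 to 2.31% and 2.60% in combination replicate 1 against 0 to 0.189%. Among the 4 named immune classes, neutrophil-like cells were 9.08% in anti-HER2 replicate 4 against 1.65 to 2.87%, and T-like cells 23.6% in combination replicate 4 against 2.49 to 5.79%.

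In macrophage-like cells, anti-HER2 replicate 4 stood apart for G0s2 (94.7 CPM against 25.8 to 28.5), Cd74 (39430 against 32229 to 32588) and Cd4 (27.3 against 17.3 to 17.9). So did anti-HER2 replicate 1 for Eno1 (464 against 380.1 to 392), anti-HER2 replicate 3 for Cxcl10 (68.2 against 87.7 to 90.6), combination replicate 1 for Adssl1 (40.6 against 28.4 to 29.5) and combination replicate 4 for Hist1h1e (22.02 against 38.8 to 41.0). In epithelial-like cells the values were 168 CPM for Sh3bgrl3 in anti-HER2 replicate 4 (224 to 236 in the others), 26.3 for Hdac1 in anti-HER2 replicate 1 (22.5 to 22.8), 166 for Rpl9-ps6 in combination replicate 4 (89.3 to 99.3), 95.0 for Gclm in combination replicate 2 (80.6 to 82.6) and 71.5 for Ly6a in combination replicate 1 (1.56 to 5.44). Fos was 848 CPM in T-like cells of anti-HER2 replicate 4 against 649 to 670.3 in the other anti-HER2 libraries.

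The direct test of anti-CD47 with and without anti-HER2 called 30 genes upward and 43 downward in macrophage-like cells. Named were Dusp2 (1.65), Cx3cr1 (0.88), Myc (0.88) and Epb41l4aos (0.88) upward, and Anxa1 (-1.29), Fam20c (-1.33), Klf6 (-0.90), Mpp7 (-1.14), Hpcal1 (-0.74), Sphk2 (-0.80), Nr1h3 (-1.85) and Acod1 (-3.47) downward. Mpp7 and Acod1 rose alike in all treated groups.

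Other splits of the libraries were fitted for each comparison with at least 3 libraries per group. For macrophage-like cells, 1 of the 35 splits, the real one, called as many genes as anti-HER2 against control (80, highest other 0), the combination against control (160, highest other 32) and the combination against anti-HER2 (23, highest other 11). This share was not adjusted over the comparisons. It argues against chance only if the libraries of a tag number are independent, and anti-HER2 libraries that share a number deviated together. Only 3 of these 35 splits keep the tag numbers whole, too few for a share under 0.05, so chance is not excluded. The same held, at 1 of 35 splits, for epithelial-like cells of anti-HER2 against control (43, highest other 26) and the combination against anti-HER2 (7, highest other 1), T-like cells of anti-HER2 against control (37, highest other 1) and monocyte-like cells of anti-HER2 (57, highest other 11) and the combination (55, highest other 7) against control. Even if libraries of a tag number are independent, chance cannot be excluded for epithelial-like cells of the combination against control (3 of 35 splits, real 79, highest other 1322), T-like cells of the combination against anti-HER2 (4 of 35, real 1, highest other 7) and monocyte-like cells of the combination against anti-HER2 (11 of 35, real 1, highest other 3). The split with 1322 genes set combination replicates 2 to 4 and control replicate 1 against the rest and points to a structure of the samples. For T-like cells of the combination against control, 10 splits are too few for a share under 0.05 (1 of 10, real 30, highest other 0).

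The 3 control libraries lay outside all others for 243 genes in macrophage-like cells (3 of 286 trios of libraries had as many, highest other 342), 196 in epithelial-like (11 of 286, highest other 1252) and 296 in stromal cells (2 of 286, highest other 402), and many of the genes called against control share sequence with another gene. Upper limits on UMIs and genes that differ between groups are argued against: inside a window that all libraries hold, the called genes kept a median of 0.997 of their log2 fold for anti-HER2 and 0.99 for the combination. Reads shared between gene copies may have been counted differently in control libraries, since the called genes that share sequence moved in stromal cells by a median of 0.942 (anti-HER2) and 0.923 (combination) of their macrophage-like log2 fold. Of the genes that rose, 54.5 and 65.3% were over 2 times higher in another class. The share in other genes was not taken, so RNA from other cells stays open. A response to antibody in all cells was not tested apart from these. Sh3bgrl3, with 0% shared sequence, is not accounted for by the sequence searched.

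In macrophage-like cells, 12 transcripts higher in epithelial-like cells rose from anti-HER2 to combination libraries. They rose by a median of 0.843 (monocyte-like), 1.47 (T-like) and 1.51 (stromal) times the macrophage-like rise. Hbegf fell in each of these, Tmsb10 in stromal and Cd24a in monocyte-like cells. Igfbp5 went from 9.86 to 144 CPM in macrophage-like cells. RNA released from epithelial-like cells may have entered these droplets. The T-like and stromal rises argue against tumour cell uptake by macrophages alone, and uptake itself was not tested.

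Epithelial-like cells of combination replicates 2 to 4 stood apart from combination replicate 1. Sequencing on another instrument is argued against, because genes 2-fold apart in epithelial-like cells differed in stromal cells by a median of 0.0830 of that difference. A difference between tumours remains open and was not tested.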

How the results depend on the processing

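Settings added after the data were seen are listed above. Across other settings, 114 counts of genes stayed within 1.5 times and 61 moved further, and with 1 library left out 155 stayed and 63 moved. Of the values of named genes, 1532 kept direction and call, 623 lost the call and 8 turned direction under other settings, and with 1 library left out 1691 kept and 629 lost it. Of all tests of shares 72 kept their side of the threshold and 1 did not: the monocyte-like share, adjusted over classes, passed at 0.00135 to 0.0251 under the other settings but not with 1 value per tag number (exact permutation p = 0.0476, adjusted p = 0.463). With 1 value per tag number, too few assignments exist for 1 class alone to pass after adjustment. The cause of the other moves was not tested except where fewer libraries or genes entered the fit.

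With genes that share sequence removed, macrophage-like cells had 10 (anti-CD47 against control), 12 (anti-HER2), 43 (combination), 12 (combination against anti-HER2), 7 (combination against anti-CD47) and 11 genes (difference of effects). Epithelial-like cells had 2, 5, 11 and 15 genes in the first 4 of these comparisons, T-like cells 8, 1 and 0 for anti-HER2 and combination against control and combination against anti-HER2 (limma, 415 at an unadjusted p under 0.05), and monocyte-like cells 2, 4 and 4 against control. With 1 value per tag number, macrophage-like counts were 26, 36, 49, 0, 0 and 23 (430 and 372 genes at an unadjusted p under 0.05 beside the counts of 0 in limma), epithelial-like 18, 19, 32 and 1, T-like 18 and 19 against control, and monocyte-like 5 for combination against anti-HER2. Relative to the epithelial-like and stromal cells, macrophage-like counts were 3, 6, 24, 14, 6 and 5. With the tag number as a random effect they were 43, 83, 8, 1 and 39 for anti-CD47 and combination against control, combination against anti-HER2 and against anti-CD47, and the difference.

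Without the filter on low values, macrophage-like counts were 340 (combination against control), 211 (against anti-HER2) and 94 (against anti-CD47), and epithelial-like 72 (anti-CD47) and 1 (combination against anti-HER2). In the common window they were 38 and 37 for combination against anti-HER2 and anti-CD47, and 205 in epithelial-like cells of combination against anti-HER2. On 1 instrument, with 1 combination library, they were 70 and 20 for macrophage-like combination against control and anti-CD47, and 31 and 4 for epithelial-like combination against control and anti-HER2. With only the groups compared, macrophage-like counts were 126 (anti-CD47), 13 and 3 (combination against anti-HER2 and anti-CD47). Macrophage-like combination against anti-CD47 had 1 gene with monocyte-like cells added, 1 with summed UMIs and 3 with a pseudocount of 10, and epithelial-like combination against anti-HER2 had 12 with median-ratio scaling, 19 with a pseudocount of 10 and 1 with summed UMIs. Lists called fell from 57 to 1 with an estimated correlation and 14 with fry in macrophage-like, from 40 to 0 and 2 in epithelial-like and from 12 to 0 and 0 in T-like cells.

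Relative to other cells, direction turned for Tpx2 (-0.082), Cd74 (0.039), Oas1a (0.37) and Rplp1 (0.035) in combination against control, Dbi (-0.31) and Oas1a (0.23) against anti-HER2, Oas1a (0.57) against anti-CD47 and Cx3cr1 (-0.20) in the difference.

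With each library left out in turn, macrophage-like counts ran from 32 to 73 (anti-CD47), 44 to 88 (anti-HER2), 71 to 201 (combination), 11 to 74 (combination against anti-HER2), 0 to 22 (against anti-CD47) and 36 to 97 (difference). Epithelial-like counts ran from 18 to 75, 33 to 46, 39 to 1067 and 1 to 1496, T-like from 26 to 38, 19 to 32 and 1 to 18, and monocyte-like from 19 to 36, 36 to 71, 36 to 65 and 0 to 8. Where a group was left with 1 library, that library was taken to vary like the other groups.

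Neither DESeq2 nor edgeR was run, since the deposited values are logs, although the recovered UMI counts would have allowed it. The random effect was fitted on log2 values rather than by voom. No paired analysis was possible because no tag number occurs in more than 1 group. In T-like cells 8 to 22% of simulated 2-fold changes were found, and monocyte-like cells were not simulated.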

Other observations

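Monocyte-like cells were tested after their shares had been seen. Acod1, the enzyme that makes itaconate, averaged 8.25 CPM in 3 control libraries, 75.02 CPM with anti-HER2 and 119 CPM with the combination (4 libraries each; log2 fold 3.08 ± 0.55 and 3.50 ± 0.55, adjusted p = 0.0227 and 0.01). The kinase Sgk1 rose from 176 CPM to 306 CPM with each (0.79 ± 0.17 and 0.76 ± 0.17, adjusted p = 0.0208 and 0.031). With anti-HER2 the G protein regulator Rgs1 (1.03 ± 0.20, adjusted p = 0.0133), the interferon-induced tether Bst2 (0.92 ± 0.19, adjusted p = 0.0227) and Rin2 (0.97 ± 0.22, adjusted p = 0.0368) rose. With the combination the scavenger receptor Cd36 (2.197 ± 0.46, adjusted p = 0.0227) and the checkpoint receptor Havcr2 (0.89 ± 0.21, adjusted p = 0.0461) rose. The adhesion molecule Jaml fell from 73.1 to 29.4 CPM (-1.31 ± 0.23, adjusted p = 0.00314), as did the aryl hydrocarbon receptor Ahr (-1.22 ± 0.25, adjusted p = 0.0143) and its target Tiparp (-0.72 ± 0.15, adjusted p = 0.015).

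Among 6901 genes tested in monocyte-like cells, 38 rose and 19 fell with anti-HER2 (45 of 57 with shared sequence) and 32 rose and 23 fell with the combination (42 of 55). With anti-CD47, 21 rose and 12 fell, Rcan1, a regulator of calcineurin, among the rises (1.37 ± 0.31, adjusted p = 0.0469). Against anti-HER2 the combination lowered 1 gene, the polyamine enzyme Sat1 (-0.63 ± 0.10, adjusted p = 0.0226), and against anti-CD47 limma called 0 genes, with 453 at an unadjusted p under 0.05. With each library left out in turn, none of the 6 genes followed for anti-HER2 kept its call, nor did Rcan1 and Sat1, and of the 8 followed for the combination only Jaml did. Without control replicate 2, with anti-HER2 Acod1 (adjusted p = 0.169), Sgk1 (0.177), Bst2 (0.184) and Rin2 (0.391) did not pass, and with the combination Acod1 (0.0786), Sgk1 (0.227), Cd36 (0.205) and Havcr2 (0.348) did not. Rgs1 did not pass without anti-HER2 replicate 1 (0.0527), and Ahr (0.145) and Tiparp (0.103) not without control replicate 1.

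The cluster of macrophage-like cells led by Gpnmb, Arg1 and Hmox1 held 31 of 517, 37 of 335 and 64 of 894 of these cells in control libraries, 108 of 345 and 135 of 515 in anti-CD47, 138 of 631, 86 of 388, 116 of 708 and 138 of 648 in anti-HER2, and 109 of 518, 74 of 641, 186 of 600 and 24 of 137 in combination libraries. These parts were not tested between groups.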
